A study of Mus musculus with 6 samples.

How the data were processed

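Messenger RNA of skeletal muscle satellite cells, the resident stem cells of muscle, was sequenced in 3 control samples and 3 samples in which the DNA methyltransferase gene Dnmt1 had been deleted (Dnmt1 KO). Per the labels, the mice carried a tamoxifen-inducible Cre recombinase under the Pax7 gene together with floxed Dnmt1 alleles, were male C57BL/6 animals of 7 weeks, and received tamoxifen or vehicle on 5 consecutive days. Which samples received which, and whether control animals carried Cre, is not given in the sources used here. The labels do not say that the samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical in part.

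Per the submitters' processing notes, reads were aligned with TopHat to the mouse genome build mm10 and counted per gene with featureCounts. The versions, the annotation, the strand setting of the counting and the method of scaling are not given in the sources used here. The library kit preserves strand, per the labels. The authors deposited 1 table of 23420 genes, whose sample columns hold a signal that is never negative: read counts multiplied by 1 factor per sample. Within each library, 100% of the values were whole multiples of the smallest value above 0, within a tolerance of 0.001. Dividing by that smallest value gave 1403242, 1437762 and 2021725 reads in control replicates 1, 2 and 3, and 954786, 1347051 and 1102065 reads in knockout replicates 1, 2 and 3. The scaled totals lay between 1351539 and 1407629. The deposited p-value and q-value columns hold the authors' own test of each gene, whose tool is not given in the sources used here. The authors' fold change column was not used here.

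The design fixed before the data were examined foresaw raw counts and named a test for other units, which applied here. Values were transformed as log2(value + 1), genes with a value of at least 1 in at least 3 libraries were kept, and the groups were compared with limma 3.58.1 in R 4.3.3 with an intensity trend and Benjamini-Hochberg adjustment at 0.05. All adjusted p-values for single genes come from this test unless another is named. A fold change on this scale understates the change of genes with low values. A gene at 0 in all 3 controls passed the filter only with a value of at least 1 in all 3 knockouts. The direction of its change was thus fixed by the filter. For a gene at 0 in all 3 controls, a fold is given as a lower bound against a floor of 3 reads over the control group, 0.859 units. Floors cover counting error only, since sequenced reads are not independent molecules. Intervals taken over genes cover no counting error and treat the genes as independent.

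Gene lists numbering 28, for pathways, cell states, RNA quality and markers of other cell types, were fixed before the data were examined, and 24 had at least 3 members tested. The list of mitochondrially encoded genes had 0 members in the table and was not used here. Older symbols matched 8 list members. Lists were tested with camera at a preset correlation of 0.01, again with a correlation estimated for each list, and with fry. The genes named were chosen by a rule fixed in advance. It took 15 genes of prior interest, the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups. It added the 4 smallest p-values in each direction beyond these and up to 4 members past the threshold in each list. Genes without an official symbol were skipped, and 11 eligible ones were passed over in this way. Genes named outside the rule are marked as chosen after their values were seen.

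The script was tested on simulated counts, with 200 of the genes changed by known folds at a dispersion of 0.0126, the median estimated from the replicates. It tested 12748 genes and recovered 82.1% of the changes of 2-fold, 97.0% of those of 4-fold and 100% of those of 8-fold, with 4 false calls among 190. Genes more variable than the median would be recovered less often. That dispersion came from genes with a group mean of at least 50, and genes with the lowest means were not among those changed. The simulated libraries were independent draws, with no library standing apart. The recovery and the false calls thus describe an easier setting than these data. For the named genes, words of 50 bases from GENCODE M21 transcripts were searched in the transcripts of other genes, as a measure of reads that counting could split between copies. Alternatives were 3 other scalings, 2 other filters, a pseudocount of 0.1, the replicate number as a block, each library left out in turn and, chosen after the data were examined, a contractile covariate and tests on recovered reads. Those tests used edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on 4 libraries, 2 per group, control replicates 2 and 3 and knockout replicates 1 and 3. Values were whole multiples in all 6, but in control replicate 1 and knockout replicate 2 the smallest value was 1.003, so near 1 that the rule applied here did not accept recovered reads. The restriction is one of this rule, not of the values. Calls of lists made only with 1 library left out were also tested with a correlation estimated in the same fit, a choice made after the data were examined.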

Results

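The expression of 23420 genes was measured by RNA sequencing in mouse muscle satellite cells, in 3 control and 3 Dnmt1 KO samples. The question was how the transcriptome of these cells differs when they lack the maintenance DNA methyltransferase. Values are scaled read counts as deposited. Control means were 811 for Mki67, a marker of dividing cells, and 1563 for the early myogenic factor Myod1. Dividing cells were thus among them, and the results need not hold for resting satellite cells. The libraries were shallow, with 954786 to 2021725 reads each, and 12484 to 13387 genes had a value above 0. Against the noise of counting reads alone, pairs of libraries within a group had a chi-square per degree of freedom of 2.39 to 12.5, which does not tell separate animals from separate preparations. The first principal component held 41.7% of the variance and the second 24.7%. Control replicate 2 stood apart from the other controls on both. On the first component the controls lay at -52.3, -0.262 and -48.4 and the knockouts at 37.3, 55.2 and 8.36. Control replicate 2 thus lay nearest to knockout replicate 3 there. On the second component it lay at 64.7, against -4.79 and -14.2 in the other controls.

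Dnmt1, which copies methylation marks onto newly made DNA, fell in every knockout library. Its value was 614, 539 and 655 in the controls and 74.6, 36.1 and 81.2 in the knockouts, or 603 ± 59.0 against 63.97 ± 24.3 (SD, n = 3 each). The log2 fold change was -3.29 (SE 0.27, adjusted p = 0.00121, limma). The gene lies on chromosome 9 at 20907206 to 20959888 (mm10, 41 exons as listed), and the value counts all exons, deleted or not. The other writers of methylation did not pass the test. Dnmt3a had a log2 fold change of -0.09 (adjusted p = 0.879) and the less abundant Dnmt3b one of -1.41 (SE 0.57, adjusted p = 0.271). Uhrf1, the partner that guides Dnmt1 to DNA, had one of -0.41 (adjusted p = 0.391), and 15.4% of its 50-base words occur in other genes. Among 19 tested members of the list of DNA methylation machinery, Dnmt1 alone passed, and it was also the only one when adjusted over the list alone. The list was called lower by camera (adjusted p = 0.0467; adjusted p = 0.245 with an estimated correlation). Without Dnmt1 the list had an adjusted p of 0.188, and with median-of-ratios scaling one of 0.0513. Equal library totals, the other filters, the pseudocount of 0.1 and the replicate block also ended the call (camera adjusted p of 0.0526 to 0.0734). Of 18 settings other than the main one, 6 called the list. The list's call ended without control replicate 2 (adjusted p = 0.102), knockout replicate 1 (adjusted p = 0.0897) and knockout replicate 2 (adjusted p = 0.0949).

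**Figure D1:**
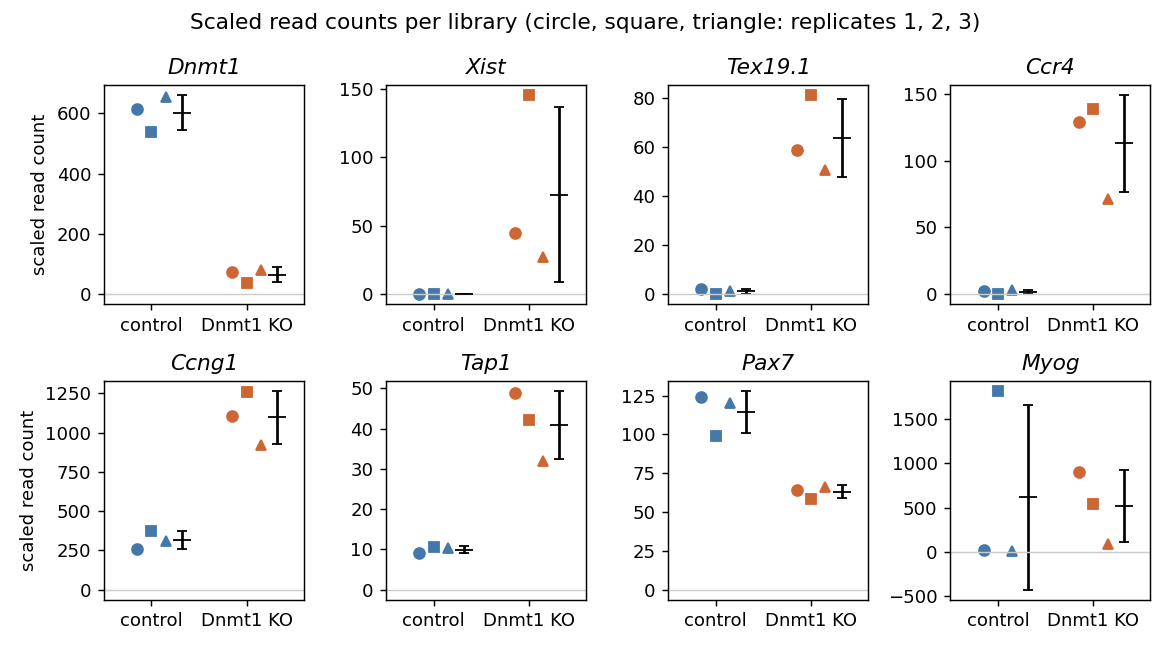
Scaled read counts of 8 named genes, with 1 point per library and, at the right of each group, the mean with its SD (n = 3); the vertical axes are linear and differ between panels. Dnmt1 lies between 36.1 and 81.2 in the knockouts and between 539 and 655 in the controls, Xist is at 0 in all 3 controls, and Myog spans 5.53 to 1821 within the controls.

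Genes that rose far outnumbered genes that fell, and the largest rises started from values near 0. Xist, the RNA that silences the X chromosome in female cells, was at 0 in all 3 controls of these male cells and at 44.4, 145 and 27.1 in the knockouts, at least 84.2-fold higher than the floor. The chemokine receptor gene Ccr4 rose from 1.59 ± 1.43 to 113 ± 36.3 (log2 fold change 5.61, SE 0.51, adjusted p = 0.00152). Tex19.1, a germ cell gene, rose from 1.13 ± 1.03 to 63.5 ± 15.9 (log2 fold change 5.04, SE 0.47, adjusted p = 0.00152). The X-linked Pet2, at 0 in all controls, reached 33.0 ± 22.7, at least 38.4-fold higher than the floor. Apol9a, also at 0 there, reached 26.8 ± 12.6, at least 31.2-fold higher. Glipr1, Scube1 and the Y-linked Uba1y rose with log2 fold changes of 4.73, 4.69 and 4.62. The smallest p-values among further rises belonged to the metalloprotease gene Adam8 (log2 fold change 4.06), to Padi3, which converts arginine residues to citrulline (4.26), and to the caspase gene Casp12 (3.58). Of 12591 genes tested, 210 were higher and 12 lower in the knockouts by limma, and 1956 had an unadjusted p under 0.05. All 222 called genes showed no overlap between the groups, as did 21.2% of the tested genes, where chance gives 10%. Of the genes that rose, 22 were at 0 in all controls and 99 had a control mean under 10. The changes of at least 2-fold were 196 rises and 4 falls. The median log2 fold change was 2.20 over the rises, and likewise 2.20 with those at 0 in the controls set to their bound. Leaving out control replicates 1, 2 and 3 in turn gave 67, 659 and 93 higher and 1, 114 and 1 lower genes. Leaving out knockout replicates 1, 2 and 3 gave 12, 18 and 72 higher and 1, 1 and 2 lower. Uba1y lost its call without knockout replicate 1 (adjusted p = 0.0502) or 2 (adjusted p = 0.0678), and Xist, Pet2, Apol9a and Scube1 were not tested with any knockout library left out. Uba1y shares 47.7% of its 50-base words with other genes and Apol9a 16.5%. Glipr1 lies opposite Krr1, and Xist opposite Tsix, which was listed at 0 in all 6 libraries.

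**Figure D2:**
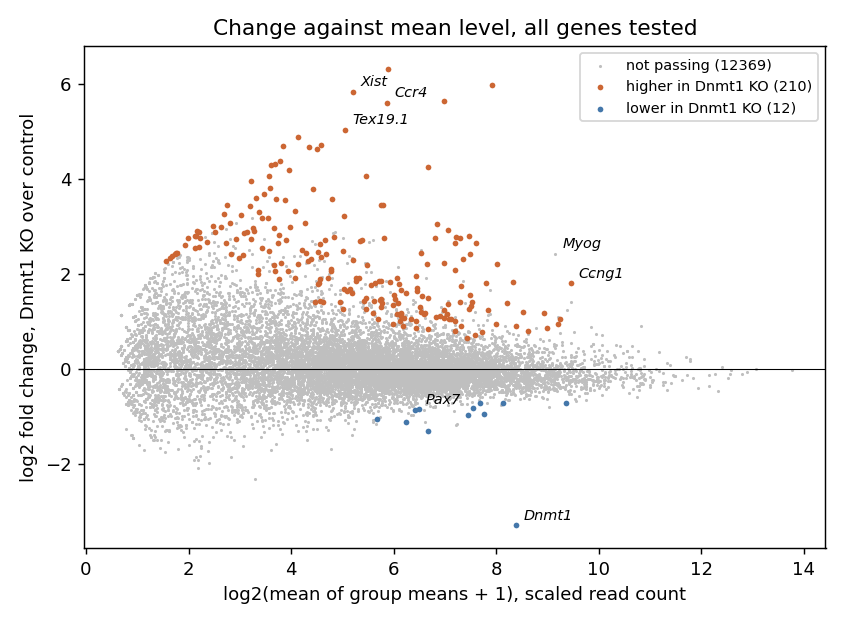
Log2 fold change of Dnmt1 KO over control against the mean level, log2(mean + 1) of the scaled read counts, for the 12591 genes tested; orange points are the 210 genes higher, blue points the 12 genes lower and grey points those not passing. Of the rises, 99 have a control mean under 10, and Dnmt1 lies apart at -3.29.

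The falls were smaller than the rises, with a median log2 fold change of -0.91. Lbh, a regulator of transcription in limb and heart development, fell from 143 ± 18.7 to 58.3 ± 13.8 (log2 fold change -1.30, SE 0.21, adjusted p = 0.0164). Adarb1, an enzyme that edits adenosine in RNA, fell by 1.11 on the log2 scale, the ubiquitin ligase component Fbxo21 by 1.05 and the spermine synthase gene Sms by 0.97. Hmgb3, Tmcc3, the imprinted gene Peg10, Sox11, Fnbp1l and Anp32e fell by 0.95, 0.87, 0.83, 0.72, 0.72 and 0.71. All 10 of these genes lost their calls without control replicate 1 (adjusted p of 0.0672 to 0.230), control replicate 3 (0.0600 to 0.195), knockout replicate 1 (0.0548 to 0.164) or knockout replicate 2 (0.0743 to 0.210). All but Sms, 9 genes, also did without knockout replicate 3 (up to 0.135). Hmgb3 and Sms share 25% and 17.5% of their words with other genes.

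Camera called targets of the tumour suppressor p53 higher as a list (adjusted p = 4.44e-14; adjusted p = 0.0984 with an estimated correlation). Of 28 tested members, 8 rose and 0 fell over all genes tested, and 23 rose adjusted over the list alone. The cell cycle regulator Ccng1 rose from 314 ± 57.3 to 1097 ± 170 (log2 fold change 1.81, SE 0.18, adjusted p = 0.00152), and Trp53inp1 from 24.5 ± 14.2 to 202 ± 77.3 (log2 fold change 3.06, adjusted p = 0.00576). Mdm2, the ubiquitin ligase that limits p53, rose from 222 ± 16.9 to 513 ± 89.1 (log2 fold change 1.19, adjusted p = 0.00921). Ephx1, an epoxide hydrolase gene, had a log2 fold change of 2.72, and Tnfrsf10b, Eda2r, Zmat3 and Ei24, named after their values were seen, made up the 8. The median of the list was 1.20, also with its 2 members at 0 in the controls set to their bound. Cdkn1a, the inhibitor of cyclin-dependent kinases induced by p53, had values of 255, 836 and 217 in controls and 949, 1126 and 587 in knockouts and did not pass (log2 fold change 1.25, adjusted p = 0.215). It passed without control replicate 2 (log2 fold change 1.86, adjusted p = 0.000334). The list of CDK inhibitors was not called, with 0 of 7 members past the test and a median of 0.61 (adjusted p = 0.410). Of its members, Cdkn1c (adjusted p = 0.380) and Cdkn2a (adjusted p = 0.841) did not pass. Ephx1 lost its call without knockout replicate 1 or 2, Trp53inp1 without knockout replicate 1 and Mdm2 without knockout replicate 2, with adjusted p up to 0.0603. Without control replicate 2, 15 of the 28 members rose.

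Of the genes of the germ line and placenta that promoter methylation keeps silent in body cells, 3 of the 16 tested rose, and 36 were too low to test. Camera called the list higher (adjusted p = 5.82e-08; adjusted p = 0.0984 with an estimated correlation). Of 52 members in the table, 38 were at 0 in all controls, and 23 of these were above 0 in at least 1 knockout library and 7 in all 3. In the other direction, 19 members were at 0 in all knockouts and 4 of these were above 0 in a control. The genes that rose were Tex19.1, the Piwi gene Piwil2 and its helicase partner Mov10l1, 0 fell, and 6 rose adjusted over the list alone. Piwil2 went from 2.21 ± 1.04 to 17.4 ± 4.59 (log2 fold change 2.55, adjusted p = 0.0221), and Mov10l1 from 0 in all controls to 4.86 ± 2.77, at least 5.66-fold higher than the floor. Dazl, a germ cell RNA-binding protein gene, was at 0 in the controls and at 1.43, 9.03 and 0 in the knockouts and was too rarely detected to test. The list had a median log2 fold change of 1.57, or 1.52 with the 7 members at 0 in the controls set to their bound. These 7 passed the filter only through their knockout values, so their rise was fixed by the filter. The median and the camera call of the list rest in part on them. Piwil2 lost its call without any library but control replicate 2 (adjusted p up to 0.142 among the knockouts). Mov10l1 lost its own without control replicate 1 (adjusted p = 0.173) or 3 (adjusted p = 0.1502) and was not tested with any knockout library left out.

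Of 25 tested genes of the interferon response and of antigen presentation, 3 rose and 0 fell, and 14 rose adjusted over the list alone. The log2 fold change was positive in 21 of the 25. A further 14 of the list's 39 members were too low to test. Among these, Mx1, Oas1a and Oas2, named after their values were seen, were at 0 in all 6 libraries. Camera called the list higher (adjusted p = 6.78e-09; adjusted p = 0.0984 with an estimated correlation). Tap1, which carries peptides to class I molecules, rose from 9.96 ± 0.807 to 41.0 ± 8.44 (log2 fold change 1.92, SE 0.29, adjusted p = 0.0126). Psmb8, a subunit of the immunoproteasome, rose from 1.49 ± 1.78 to 15.9 ± 8.65 (log2 fold change 2.91, adjusted p = 0.0485), and Ifi27l1 from 9.24 ± 1.73 to 43.3 ± 14.5 (log2 fold change 2.07, adjusted p = 0.0169). The list median was 0.96, also with 2 members at their bound. All 3 genes lost their calls without control replicate 1, knockout replicate 1 or knockout replicate 2 (adjusted p up to 0.199), and Psmb8 also without knockout replicate 3 (adjusted p = 0.101).

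**Figure D3:**
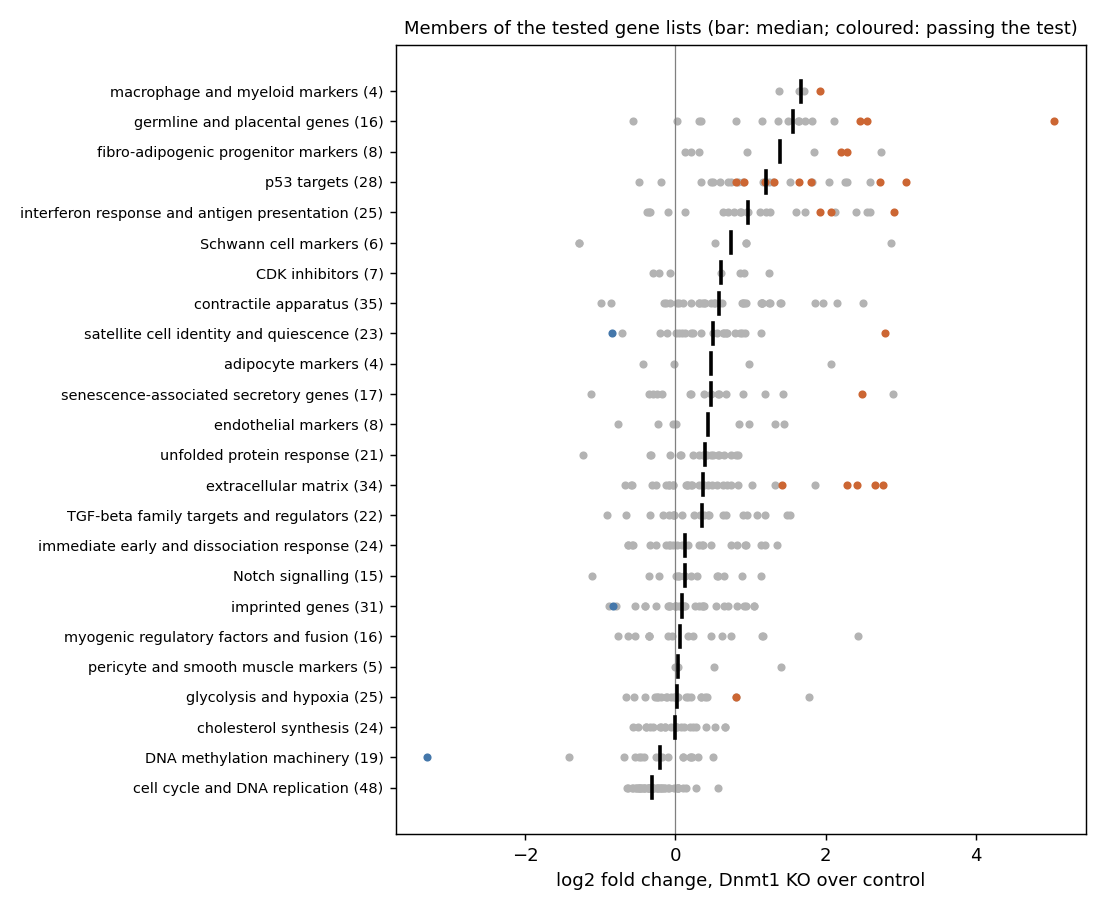
Log2 fold change of Dnmt1 KO over control for the tested members of the 24 lists, with the number tested in brackets; each point is a gene, orange and blue points pass the test as higher or lower, grey points do not, and the bar is the list median. The median is 1.20 for p53 targets, 1.57 for germline and placental genes and -0.31 for cell cycle genes.

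Pax7, the transcription factor that marks satellite cells and drives the Cre recombinase here, fell from 115 ± 13.6 to 63.1 ± 4.32 (log2 fold change -0.85, SE 0.17, adjusted p = 0.0441). Whether the controls carried Cre is not given. An effect of the Cre allele on Pax7 itself therefore cannot be told from one of losing Dnmt1. Gpx3, an antioxidant enzyme gene of the list of satellite cell identity and quiescence, rose from 32.8 ± 11.03 to 263 ± 177 (log2 fold change 2.78, adjusted p = 0.0157). These were the 2 genes past the test among 23 tested members, and the list was not called (median 0.50, adjusted p = 0.189). The early myogenic factors Myf5 (log2 fold change -0.77, adjusted p = 0.184) and Myod1 (-0.35, adjusted p = 0.331) did not pass. Myog, which drives differentiation, had values of 24.1, 1821 and 5.53 in controls and 905, 547 and 92.3 in knockouts (adjusted p = 0.525). Control replicate 2 stood apart in contractile genes, with a mean log2 value of 7.99, against 4.40 and 3.78 in control replicates 1 and 3 and 6.77, 6.77 and 4.74 in the knockouts. With all libraries, 0 of 35 contractile genes passed (1 rose adjusted over the list alone; median 0.59, camera adjusted p = 0.173), but the list was called higher without knockout replicate 3 (adjusted p = 0.00456; adjusted p = 0.756 with an estimated correlation). Of 16 myogenic factors, 0 passed (0 higher and 1 lower adjusted over the list alone). Without control replicate 2, 20 of 33 contractile genes rose (camera adjusted p = 2.31e-09; adjusted p = 0.555 with an estimated correlation) and Myog passed as higher (log2 fold change 4.81, adjusted p = 0.00123), as did Myf5 as lower (-1.002, adjusted p = 0.0140). The list of myogenic factors had a median of 0.06 and a mean of 0.24, while camera put it lower (adjusted p = 0.418). In 3 of 18 other settings camera called it (lowest adjusted p = 0.00236). Pax7 and Gpx3 lost their calls without control replicate 1 or 3 or without knockout replicate 1 or 2, and Pax7 without knockout replicate 3, with adjusted p up to 0.211. Without control replicate 2 the identity list was called higher (adjusted p = 0.0192; adjusted p = 0.330 with an estimated correlation), with 6 rises and 1 fall.

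Cell cycle and replication genes lay slightly lower as a list, with a median log2 fold change of -0.31. None of the 48 members passed singly, over all genes or adjusted over the list alone, and Mki67, a marker of dividing cells, had 811 ± 133 in controls and 808 ± 162 in knockouts (adjusted p = 0.979). Camera called the list lower (adjusted p = 5.21e-05; adjusted p = 0.706 with an estimated correlation). The mean log2 value of the list was 7.91, 7.66 and 7.96 in control replicates 1, 2 and 3, and 7.72, 7.25 and 7.79 in the knockouts. Without knockout replicate 2 the call ended (adjusted p = 0.0958).

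**Figure D4:**
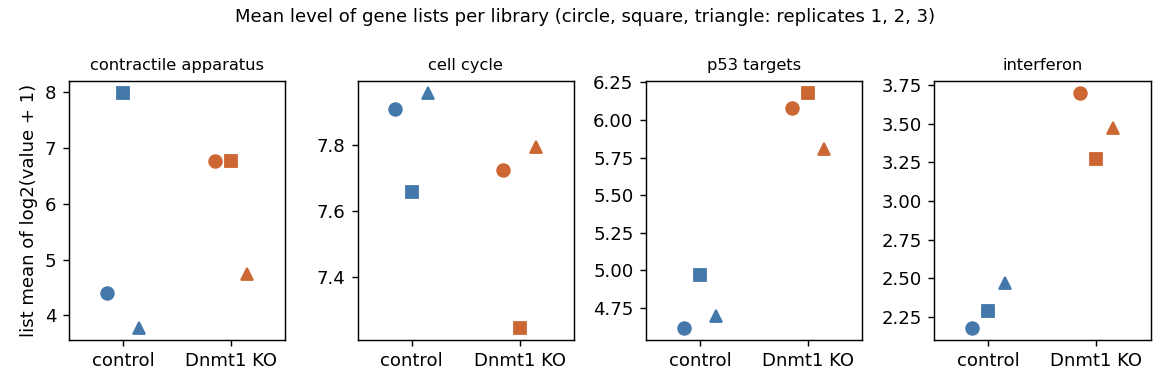
Mean of log2(value + 1) over the members of 4 gene lists, with 1 point per library; the vertical axes are linear, differ between panels and do not start at 0. Control replicate 2 lies at 7.99 for contractile genes, above every other library, while all 3 knockouts lie above all 3 controls for p53 targets and interferon genes.

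Several genes of the extracellular matrix rose, mostly collagens and secreted glycoproteins. Of 34 tested members of that list, 5 rose, 0 fell, and 9 rose adjusted over the list alone (median 0.37, camera adjusted p = 0.0141; adjusted p = 0.400 with an estimated correlation). Col1a2 rose from 55.2 ± 16.8 to 301 ± 97.6 (log2 fold change 2.42, SE 0.27, adjusted p = 0.00380), and Fbln2, Thbs2, Col6a3 and Col1a1 had log2 fold changes of 1.42, 2.65, 2.76 and 2.28. Knockout replicate 2 stood apart in some of these: Thbs2 had 156, 527 and 97.2 in the knockouts (260 ± 233, against 33.1 ± 14.0 in controls) and Col6a3 had 142, 579 and 117 (279 ± 260, against 33.7 ± 17.3). Fn1, named after its values were seen, had 155, 976 and 246 there and did not pass (adjusted p = 0.926). Col1a1 and Gsn (log2 fold change 2.20) were also the members that rose among 8 tested markers of fibro-adipogenic progenitors, the resident fibroblasts of muscle (3 adjusted over the list alone; median 1.40, camera adjusted p = 0.0108; adjusted p = 0.400 with an estimated correlation). Laptm5, a lysosomal gene of blood cells, rose from 25.3 ± 8.52 to 106 ± 63.5 (log2 fold change 1.92, adjusted p = 0.0391). It was the 1 riser among 4 tested macrophage markers (4 adjusted over the list alone; median 1.67, or 1.69 with 1 member at its bound, camera adjusted p = 0.00312; adjusted p = 0.155 with an estimated correlation). The 16 others of that list were too low to test, and of the 4 tested, 1 passed the filter only through its knockout values. No member passed among 8 endothelial, 5 pericyte, 6 Schwann cell, 4 adipocyte, 2 tenocyte and 1 erythroid markers tested. Adjusted over the list alone, 1 endothelial, 1 Schwann cell and 1 adipocyte gene rose. Without their called members, neither the matrix list (adjusted p = 0.302) nor that of fibro-adipogenic progenitors (adjusted p = 0.172) was called, while the 3 macrophage markers left without Laptm5 still were, as higher (adjusted p = 0.0201). Of the lymphocyte list, 0 of 11 members were high enough to test. All 7 genes named here as rising lost their calls without knockout replicate 1 (adjusted p from 0.0502). Without control replicate 1 or knockout replicate 2, 6 of them did, all but Col1a2 (adjusted p up to 0.181 and 0.232). Of the 7, 5 did without control replicate 3, all but Col1a2 and Fbln2 (up to 0.144). Without knockout replicate 3, 5 did, all but Col1a2 and Thbs2 (up to 0.0968).

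Of the remaining lists, the unfolded protein response was called higher by camera (median 0.39, adjusted p = 0.0141; adjusted p = 0.245 with an estimated correlation), although 0 of 21 members passed over all genes. Adjusted over the list alone, 4 were higher and 1 lower, and the call ended without control replicate 2 (adjusted p = 0.0678). Imprinted genes were not called (median 0.08, adjusted p = 0.823): Peg10 fell, and the growth-restraining RNA H19 had 8712 ± 3309 in controls and 8419 ± 1498 in knockouts (adjusted p = 0.999). Igfbp4, a binding protein of insulin-like growth factors, rose from 9.14 ± 5.31 to 53.7 ± 19.6 (adjusted p = 0.0232) as the 1 of 17 senescence-associated genes to pass (4 higher and 1 lower adjusted over the list alone; list adjusted p = 0.136). That list was called higher without control replicate 3 (adjusted p = 0.0436) or knockout replicate 1 (adjusted p = 0.0261), with adjusted p = 0.483 and 0.408 with an estimated correlation. Hk1, which starts glycolysis, rose from 286 ± 27.1 to 500 ± 45.7 (adjusted p = 0.0260) among 25 genes of glycolysis and hypoxia (2 adjusted over the list alone), a list with a median of 0.02 that camera put lower (adjusted p = 0.920). No gene passed in the TGF-beta (22 tested, 5 higher adjusted over the list alone, list adjusted p = 0.0685), Notch (15, list adjusted p = 0.831), cholesterol synthesis (24, list adjusted p = 0.749) or immediate early (24, list adjusted p = 0.405) lists. The TGF-beta list was called higher without control replicate 3 (adjusted p = 0.0225) or knockout replicate 3 (adjusted p = 0.0492), with adjusted p = 0.479 and 0.358 with an estimated correlation. Hk1 lost its call without any library but control replicate 2, and Igfbp4 without control replicate 3 or knockout replicates 1 or 2, with adjusted p up to 0.146. By fry, which asks whether the genes of a list move one way on balance and compares them with no other genes, 6 of the 9 lists called by camera passed. Those of the cell cycle (adjusted p = 0.443), of fibro-adipogenic progenitors (adjusted p = 0.227) and of the extracellular matrix (adjusted p = 0.0750) did not. In the authors' deposited table, 332 genes were called higher and 19 lower, of which 215 were also called here, 136 were not, and 7 genes were called only here.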

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

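The covariate, the tests on 4 libraries, the estimated correlations with 1 library left out and the lists without called members were chosen after the data were examined. The planned count tests on all 6 libraries (TMM with edgeR, DESeq2 and limma-voom) were not run: all 6 libraries held whole multiples, but the rule applied here did not accept recovered reads where the smallest value was 1.003, in control replicate 1 and knockout replicate 2. Dnmt1 expression kept its direction and its call in every setting run but limma-voom on 4 libraries (-2.93, adjusted p = 0.0579), and its log2 fold change was -3.51 to -2.93 with 1 library left out. The main counts, 210 higher and 12 lower, became 191 and 12, 204 and 12, and 223 and 8 under 3 other scalings, which moved the median of all genes by less than 0.1. They became 121 and 6 with a pseudocount of 0.1, 542 and 102 with the contractile covariate, and 4 lower genes were left at 2-fold or more. Leaving out 1 library gave 12 to 659 higher and 1 to 114 lower genes, highest without control replicate 2; fewer samples also lower the power. On 4 libraries limma-trend called 10 and 1, edgeR 5 and 1 (100% of values whole), DESeq2 34 and 1, and limma-voom 0 and 0, with 592 at an unadjusted p under 0.05. The cause of these shifts was not tested beyond the smaller number of samples. Of the 9 lists called, 0 were with an estimated correlation. Some lists not called in the main setting were called in some of the 18 others. These were TGF-beta in 7, senescence-associated genes in 6, contractile genes in 4, myogenic factors in 3 and satellite cell identity in 1. With the replicate number as a block, 359 and 76 genes were called. Same-numbered libraries correlated at -0.06, 0.22 and 0.31 in their deviations from the group means. Control replicates 2 and 3 correlated best with their same-numbered knockouts (next best 0.14 and -0.14), but control replicate 1 with knockout replicate 3 (0.19). Whether the numbers pair the samples thus stays open. The labels do not say that they do, so the main test has no block. Myog, at 2.43 on all 6 libraries, reversed to -0.91 by edgeR and -0.93 by DESeq2 on 4 libraries. Genes with main changes of -0.22 to -0.00 also changed sign: Dnmt3a (-0.239 to 0.0849 with 1 library left out) to 0.0109 without control replicate 2, 0.0849 without knockout replicate 2, and 0.00825, 0.00412 and 0.0283 by limma-trend, edgeR and limma-voom on 4 libraries; Cdkn2a (-0.611 to 0.133) to 0.133 without knockout replicate 3; H19 (-0.177 to 0.293) to 0.0334 with equal totals, 0.293 without control replicate 2 and 0.0158 and 0.117 without knockout replicates 2 and 3; and Mki67 (-0.125 to 0.161) to 0.0190 with equal totals, 0.116 without control replicate 3, 0.161 without knockout replicate 2, 0.0398 with the covariate and 0.0876, 0.0716, 0.0804 and 0.0502 by limma-trend, edgeR, limma-voom and DESeq2 on 4 libraries. The cause was not tested. Other results for named genes kept their direction: 604 stayed on the same side of the threshold, 273 were no longer past it and 8 newly passed. At these depths, a gene with under 3 reads over a group cannot be told from one at 0.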

Other observations

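The families in this paragraph were chosen after their values were seen, so no test of their enrichment is given. Among guanylate-binding protein genes, induced by interferon, 5 of the 8 tested rose. Gbp4 rose from 61.7 ± 53.8 to 328 ± 126 (log2 fold change 2.66), and Gbp6, Gbp8, Gbp9 and Gbp10 had log2 fold changes of 2.75, 2.70, 2.23 and 2.64. Gbp10 and Gbp6 share 84.1% and 70.7% of their 50-base words with other genes and Gbp8 shares 18.1%, so these are not 5 independent signals. Control replicate 2 lay above the other controls, toward the knockouts, in all 5: Gbp4 had 28.1, 124 and 33.2 in controls, Gbp6 5.02, 32.4 and 9.68, Gbp8 5.02, 28.6 and 4.84, Gbp9 28.1, 99.0 and 22.8, and Gbp10 1.00, 3.81 and 2.77. Of 9 genes for peptide loading and the immunoproteasome, Psmb8, Tap1, Tap2 and Tapbp rose, Tap2 from 101 ± 30.7 to 265 ± 40.8. Apol9a and Apol9b rose among 4 tested apolipoprotein L genes, but 52.3% of the words of Apol9b occur in other genes, mostly Apol9a. Slfn3 and Slfn8 rose among 5 schlafen genes, Col18a1, Col1a1, Col1a2 and Col6a3 among 30 collagen genes, and 0 of 3 Xlr genes passed.

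The single genes named next were also chosen after their values were seen. Mlkl, the executor of necroptosis, went from 15.9 ± 4.90 to 62.1 ± 14.3 (log2 fold change 1.92, adjusted p = 0.0157), and Ripk3, the kinase that activates it, from 8.96 ± 2.54 to 36.6 ± 12.6 (log2 fold change 1.89, adjusted p = 0.0387). Tdrd9, a helicase of the germ line that acts with Piwi proteins, rose from 1.64 ± 1.52 to 19.8 ± 4.79 (adjusted p = 0.0232). The T cell costimulation gene Cd80 rose from 0.952 ± 1.65 to 28.1 ± 5.14 (adjusted p = 0.00839). The Trp53 gene itself had 278 ± 46.6 and 268 ± 32.04 (adjusted p = 0.919).

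For the patterns that follow, the tests of scaling, other cell types, a wrong label, differentiation and X-linked genes, and the values with 1 library left out, were chosen after the results were seen. Called genes rose far more often than they fell, and a global scaling difference stays open: rises were at least 94.1% of the calls under 3 other scalings, but these moved the median of all genes by at most 0.03, too little to reverse the sign of any called gene. Falls hidden by low baselines do not account for all of it: among 47 called genes with a control mean of at least 64, 74.5% rose (95% exact binomial interval over genes 59.7 to 86.1), and 146 of 246 did without control replicate 2. With another library left out the calls were only 4 to 13, too few to add to this. Other splits of the 6 samples are too few, at 10, for a share under 0.05. Each of the 9 others also keeps 2 of the 3 libraries of each group together. They thus hold part of any genotype difference and give no rate of false calls. Of the 10 splits, 1 gave as many genes in its larger direction (210, highest other 155) and 2 gave as many in the smaller (12, highest other 15). As many lists by preset camera came from 2 (9, highest other 12), and the 9 others called 3 lists or more each. The number of lists therefore does not set the real split apart, and it cannot tell whether the list calls are false. The split with 155 put control replicate 2 with knockout replicates 1 and 2, which points to a structure of the samples other than genotype. These 3 libraries had the highest mean log2 values of contractile genes, at 7.99, 6.77 and 6.77. Control replicates 1 and 3 and knockout replicate 3 had 4.40, 3.78 and 4.74. Contractile level was thus uneven between the groups, and its part in the main contrast cannot be fully told from that of genotype. All 222 called genes stayed called with the contractile covariate, and likewise without control replicate 2. The calls were thus kept under an adjustment for contractile level as this list scores it, which covers no other structure of the samples. A loss of silencing after Dnmt1 deletion may underlie the rises, as an untested hypothesis.

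Genes used as markers of immune cells and fibroblasts rose, among them Ccr4, Laptm5 and Col1a2; the other markers named here were picked after their values were seen. Lymphocytes in the knockout preparations would bring their other transcripts, but the median knockout level over the 11 lymphocyte markers was 0, and the highest was Lck at 0.812, against 113 for Ccr4. Over all 20 macrophage markers the median was 0 (bootstrap upper bound 0.406) against a rise of 81.0 for Laptm5, although Cd68 (6.25), Fcer1g (5.86) and Cd14 (2.86) lay above most others. The list without Laptm5 stayed called higher (camera adjusted p = 0.0201). That call rests on 3 members, of which 1 passed the filter only through its knockout values. Over all 14 markers of fibro-adipogenic progenitors the median was 3.22, with a bootstrap upper bound of 24.2 only just below the 24.6 set as a limit. That limit was set after the values were seen, and a median over genes does not measure a share of cells. Fibroblasts therefore stay open: Dcn stood at 0.478 and Lum and Dpt at 0 in the knockouts, but Col3a1 (452), Gsn (416), Col1a1 (32.1), Smoc2 (24.2) and Cd55 (18.2) were high there. Only Gsn and Col1a1 among them passed the test as higher, from control means of 102 and 5.84. Expression of the marker genes by the satellite cells themselves may be the source, a hypothesis that was not tested.

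Control replicate 2 stood apart in contractile genes. A knockout library under the wrong label is argued against by its Dnmt1 value of 539, where the highest knockout had 81.2. Adult muscle fibres carried over stay open. Myh1, Myh2, Myh4, Pvalb and Actn3 together reached 19.4% of the embryonic myosin gene Myh3 (3787) in that library, between the bounds set beforehand. Of these, Actn3 had 476 and Myh1 256 in control replicate 2, while Myh4 and Pvalb had 0.952 each and Myh2 0. Actn3 also had 140 and 119 in control replicates 1 and 3, where Myh1 had 5.02 and 0.691. A second set, chosen after the 19.4% was seen, without Actn3 and Myh2 and with Ckm, gave 7.64% and settles nothing. Further differentiation of its cells stays open too: 39 of 48 cell cycle genes had their lowest control value there, where chance gives 16, but at an estimated correlation of 0.625 these weigh as 1.58 independent genes. Myog (1821, against 24.1 and 5.53 in control replicates 1 and 3), Tmem8c (329, against 25.1 and 15.9) and Mef2c (91.4, against 2.01 and 1.38) lay highest there. Myf5 (242, against 332 and 467) lay lowest, and Jam2 (96.2, against 131 and 80.2) between. These myogenic genes were picked after their values were seen. Most of them go with further differentiation, but 1 library does not settle it. The labels give no difference between the controls, so no explanation from the design was tested.

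Xist rose in cells labelled male, and a hypothesis is that it silenced X-linked genes in all cells. The median log2 fold change of 442 X-linked genes exceeded that of 12142 autosomal genes by 0.0571 (95% bootstrap interval over genes -0.00 to 0.12; 0.0103 to 0.0731 with 1 library left out), which argues against a loss of expression of X-linked genes as a whole. Silencing in a small share of cells, or of single genes, stays open. Of the genes tested that the table lists on the Y chromosome, Ddx3y, Eif2s3y, Kdm5d and Uty had log2 fold changes of -0.20 to 0.27 and Erdr1 one of -0.58 (adjusted p = 0.914), none of them past the test, while Uba1y, which shares 47.7% of its words with other genes, rose (log2 fold change 4.62).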
